A study of Homo sapiens with 9 samples.

How the data were processed

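RNA was sequenced from 9 cultures of HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen and takes up plasmids readily. Per the labels, 3 libraries came from cells given an empty FLAG vector (Vector), 3 from cells overexpressing the kinase PLK2, and 3 from cells overexpressing PLK2(D223N), a form with a substitution in the kinase domain. Kinase activity was not measured here. The labels call the 3 libraries of a group biological replicates. Groups were taken from the sample labels alone. One Vector library has a title with transposed letters, and its column in the table was matched to it by its number and the titles of the remaining Vector libraries.

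Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads. Per the submitters' processing notes, the tools were Bowtie2, RSEM 1.3.1 and DESeq2 1.4.5, and the genome build was GRCh38.p13. The role of each tool, the gene annotation and the strand setting are not given in the sources used here. The deposited table holds estimated counts per gene, which need not be whole numbers, and per the file headers also TPM, FPKM and scaled counts. Per library, between 87.1% and 88.5% of the estimated counts lay within 0.005 of a whole number. The deposited TPM values were made by the authors. They were used here for the TPM alternative test and for the TPM level of PLK2 alone. The table holds 18 further per-library columns of FPKM and scaled counts that were not used here. It lists 17083 genes, of which 17025 matched the RefSeq gene table by NCBI gene identifier and 16971 of these are protein-coding. Genes encoded by the mitochondrial genome were not analysed here.

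The estimated counts were rounded to whole numbers. Genes were kept by filterByExpr on the group, which left 12924 genes, and libraries were scaled by TMM. All 9 libraries entered a quasi-likelihood model in edgeR 4.0.16 (glmQLFit and glmQLFTest, robust) with the group as the only term, so that the 3 comparisons shared an estimate of the spread. P-values are two-sided and adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. Fold changes are log2 values with their standard error (SE). Levels are CPM on the TMM scale, as mean ± SD over 3 libraries, save the sums of marker genes, which are CPM without TMM scaling. R 4.3.3, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15 were used.

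A set of 28 gene lists was fixed from textbook knowledge before the data were examined, including 4 lists of markers of other cell types. Lists with at least 5 tested members were tested with camera from limma on log CPM, two-sided, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. The test was repeated with the correlation estimated for each list. Members were counted by the gene test and again adjusted over the list alone. The genes named in the text also followed a rule fixed beforehand. It takes PLK2, the other polo-like kinases, HSP90AA1, HSP90AB1 and IKBKB, then up to 10 called genes with the largest change in each direction, with a mean of at least 1 CPM and no overlap between libraries of the groups compared, then up to 4 members of each list with the smallest p. Some genes outside that rule are also given, among them list members too low to test, CCL5 and genes pointed out in a figure.

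The alternatives fixed before the data were examined were DESeq2 size factors, the DESeq2 Wald test, no filter beyond 1 count, a stricter filter (10 counts in every library of a group and a mean of 1 CPM), a term for the replicate number, a fit to the 6 libraries compared, the removal of PLK2 before scaling, an estimated correlation in the list tests, and the removal of each library in turn. After seeing the data, further alternatives were added. These were the removal of trends with GC content and gene length in each library (loess, span 0.3), limma on log2(TPM + 1) for genes with a mean TPM of at least 1, list tests with PLK2 left out, and list tests with an estimated correlation without Vector replicate 1. GC content and length came from GENCODE release 29, which gave both for 12600 of the tested genes.

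The tests were tried on simulated counts with the means, library sizes and dispersions of these data. In PLK2 vs Vector, 77.6% of 67 genes changed by 0.5 on the log2 scale were called, as were 87.9% of 66 genes changed by 1 and 100% of 66 genes changed by 2, among 12862 genes tested. False calls made up 5.38% of the calls there. In PLK2(D223N) vs Vector, 69.7% of 66 genes changed by 0.5 were called, and in PLK2 vs PLK2(D223N) 77.6% of 67 genes. The simulation drew each gene independently, with the same spread in all groups and with many changed genes. It lacked the wider spread of the Vector libraries and trends shared between genes. These rates may thus be too high for the real comparisons, and few calls there do not show that few genes changed.

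Library totals ran from 14288165 to 16510186 estimated counts. A count of 3 corresponds to between 0.182 and 0.210 CPM. Intervals on counts cover counting error only, and not the variation between cultures. They also take reads as independent, which reads copied by PCR are not. Counts cannot part the plasmid's PLK2 transcript from the endogenous one. Genes with near-identical copies, such as RGPD2 and the histone genes, share reads with those copies, so their values are uncertain.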

Results

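The transcriptomes of 9 HEK293T libraries were compared, 3 with an empty vector, 3 with PLK2 and 3 with PLK2(D223N). Totals were 15632095 ± 1181989 estimated counts in Vector, 16093891 ± 106972 in PLK2(D223N) and 16104575 ± 51078 in PLK2 libraries (SD, n = 3 each). The series title concerns PLK2 in microglial activation through HSP90α and IKKβ, and the comparisons ask which transcripts change with the kinase and which need an intact kinase domain. The Vector libraries stood further apart than the others. The chi-square per gene between Vector replicates 1 and 2 was 18.1 and between replicates 1 and 3 it was 10.97, against 2.71 for replicates 2 and 3 and between 1.64 and 2.83 for the 6 pairs within the PLK2 and PLK2(D223N) groups.

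PLK2 RNA itself followed the labels. PLK2 (NCBI gene 10769, GRCh38 chromosome 5, 58453982 to 58460260 in GENCODE release 29, minus strand) was at 3.42 ± 0.64 CPM in Vector libraries. It was at 12358 ± 1650 CPM in PLK2(D223N) and at 23744 ± 2384 CPM in PLK2 libraries (SD, n = 3 each). The log2 fold change against Vector was 12.77 (SE 0.16, adjusted p = 4.35e-17) for PLK2 and 11.83 (SE 0.16, adjusted p = 1.00e-16) for PLK2(D223N). PLK2 RNA was also higher in PLK2 than in PLK2(D223N) libraries, by 0.94 on the log2 scale (SE 0.09, adjusted p = 4.99e-05), so the constructs were not matched in RNA level. In single libraries PLK2 took from 1.08% (95% Wilson interval 1.07 to 1.08) to 2.55% (2.54 to 2.56) of all counts with a construct.

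**Figure D1:**
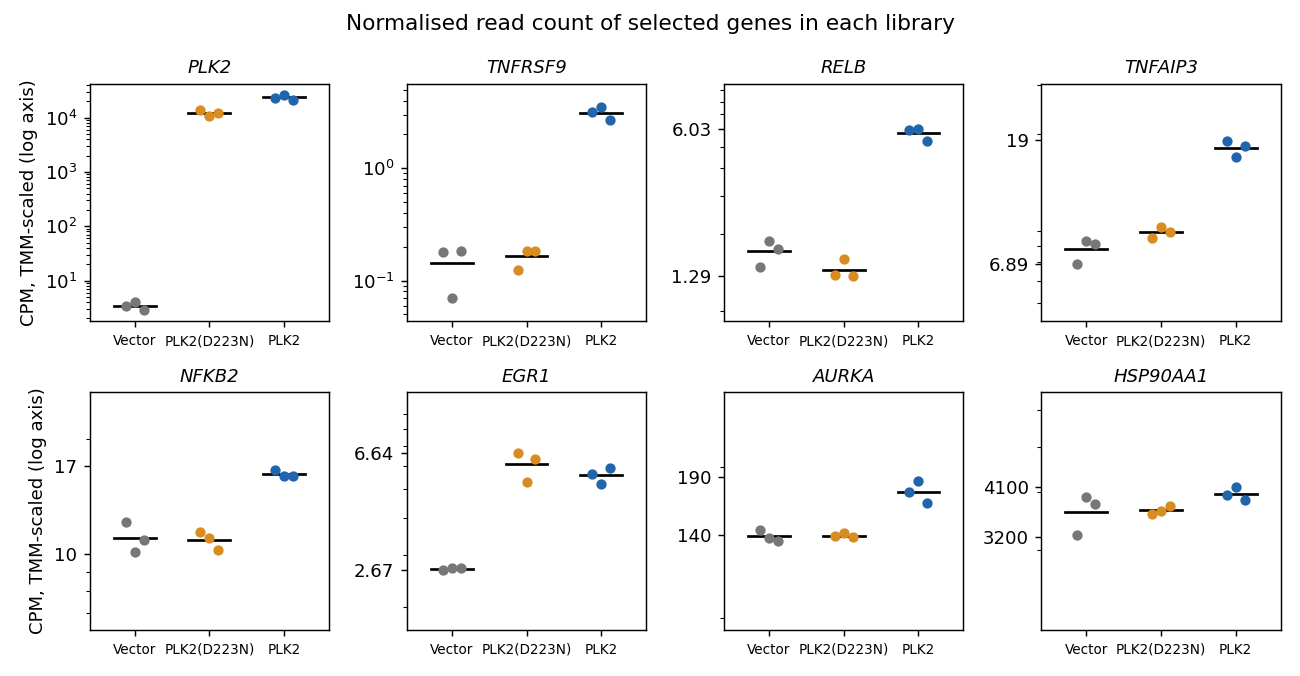
CPM on the TMM scale (log axis, ranges differ between panels) of 8 genes in each of the 9 libraries, with a bar at the mean of each group. TNFRSF9, RELB, TNFAIP3, NFKB2 and AURKA are higher in every PLK2 library than in any Vector or PLK2(D223N) library, EGR1 is higher with either construct, and HSP90AA1 overlaps between Vector and PLK2 libraries.

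With PLK2, genes of the NF-kB pathway rose against Vector. TNFRSF9, a costimulatory receptor of the TNF receptor family (chromosome 1, 7915894 to 7943165), rose from 0.144 ± 0.065 to 3.13 ± 0.42 CPM (SD, n = 3 each). RELB, the non-canonical NF-kB subunit (chromosome 19, 45001430 to 45038198), rose from 1.67 ± 0.23 to 5.77 ± 0.38 CPM, a log2 fold change of 1.79 (SE 0.16, adjusted p = 1.69e-05). TNFAIP3, which encodes the deubiquitinase A20, a feedback inhibitor of NF-kB, rose from 7.78 ± 0.77 to 17.8 ± 1.2 CPM, a log2 fold change of 1.20 (SE 0.09, adjusted p = 6.49e-06). NFKB2, the p100 precursor, and CYLD, another deubiquitinase of the pathway, rose by 0.55 (SE 0.09) and 0.42 (SE 0.06). NFKB2 did not pass without PLK2 replicate 1, 2 or 3 (highest adjusted p = 0.0666). TNFRSF9 rests on 148 counts in PLK2 and 7 in Vector libraries, a ratio of 21.2 with an exact 95% counting interval of 10.04 to 53.7.

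In all, 66 of 12924 tested genes changed between PLK2 and Vector, 62 higher and 4 lower. PLK2 aside, 18 changed at least by a factor of 2. The libraries of both groups did not overlap for any of the 66, which the call nearly fixes, nor for 20.1% of all tested genes, where chance gives 10%. Among genes with a mean of at least 1 CPM over all 9 libraries, and besides TNFRSF9, RELB and TNFAIP3, the largest rises were in DNAH17, an axonemal dynein heavy chain (log2 fold change 2.87, SE 0.26, adjusted p = 2.42e-05), and PLA2G4C, a cytosolic phospholipase A2 (2.46, SE 0.20, adjusted p = 1.00e-05). They were followed by NPR3, a natriuretic peptide receptor (1.53, SE 0.24), TP63, a relative of p53 (1.43, SE 0.28), FILIP1L (1.26, SE 0.25) and DHRS2, a short-chain dehydrogenase (1.12, SE 0.12). RGPD2, at 2.13 (SE 0.38), belongs to a family of near-identical genes and is uncertain. The 4 lower genes were ADGRB2, an adhesion receptor (-0.56, SE 0.10), NAB2, a corepressor of EGR proteins (-0.52, SE 0.09), LRRC20 (-0.40, SE 0.08) and the homeobox gene HOXA9 (-0.38, SE 0.06). None of these 4 passed without PLK2 replicate 1, 2 or 3, and ADGRB2 and NAB2 did not without Vector replicate 3, nor LRRC20 without PLK2(D223N) replicate 1, 2 or 3 (highest adjusted p = 0.210, for LRRC20). Among the higher genes, NPR3 did not pass without PLK2 replicate 1 or 3 (highest adjusted p = 0.0591) and RGPD2 without any 1 PLK2 library or Vector replicate 3 (0.0994). TP63 did not pass without Vector replicate 3, any 1 PLK2(D223N) library or PLK2 replicate 2 or 3, and FILIP1L without Vector replicate 3, PLK2(D223N) replicate 1 or any 1 PLK2 library (0.210 for both).

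Of the 27 tested members of the list of NF-kB targets, 5 rose, none fell and 22 did not pass the test in PLK2 vs Vector. Adjusted over the list alone, 10 were higher and 1 was lower. The list's median log2 fold change was 0.16, and camera gave an adjusted p of 8.13e-06, or adjusted p = 0.0314 with an estimated correlation. NFKBIA, the inhibitor IκBα, was at a log2 fold change of 0.40 (SE 0.09) with adjusted p = 0.0511, and it passed in 7 of 17 alternatives, among them those without Vector replicate 1 (adjusted p = 0.000236) and Vector replicate 2 (0.0197). Of the cytokine genes of the list, CSF1 (0.28, SE 0.09, adjusted p = 0.185) and CCL5 (-0.28, SE 0.27, adjusted p = 0.590) were tested and did not pass, though CSF1 was higher when adjusted over the list alone. Others had few counts. CXCL8 had 13 counts over the PLK2 libraries and 2 over the Vector libraries, a ratio of 6.52 with an exact 95% counting interval of 1.48 to 59.5, and was too low for the gene test. That interval does not allow for the choice of CXCL8 among several untested genes. Other chemokine genes too low to test did not all rise. In PLK2 and Vector libraries CXCL1 had 0 and 1 counts, CXCL2 8 and 5, and CXCL3 8 and 9. CXCL10 had 6 and 5 there, and CXCL11 1 and 2. IL6 and TNF reached at most 3 and 1 counts in any library and were not tested. Of 32 NF-kB signalling components, 3 rose (RELB, NFKB2 and CYLD, which the list of targets also holds), with adjusted p = 0.0976 for the list (0.296 with an estimated correlation). With the preset correlation it was 0.00789 without Vector replicate 1 and 0.0391 without PLK2 replicate 2. IKBKB, which encodes IKKβ, differed by 0.01 (SE 0.07, adjusted p = 0.962).

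Genes of mitosis also rose with PLK2. Of 45 members of the list of G2/M genes, 6 rose, none fell and 39 did not pass. Adjusted over the list alone, 28 were higher and none was lower. The median log2 fold change was 0.21, with adjusted p = 7.11e-18 by camera and adjusted p = 0.0314 with an estimated correlation. HJURP, the chaperone of the centromeric histone CENP-A, rose by 0.35 (SE 0.05), the mitotic kinase AURKA by 0.34 (SE 0.05), HMMR by 0.50 (SE 0.08) and the kinesin KIF18A by 0.53 (SE 0.09). Single genes did not all pass with a library left out. HJURP and KIF18A lost their call without PLK2 replicate 1, 2 or 3 (highest adjusted p = 0.0756 and 0.106), AURKA without Vector replicate 3 or PLK2 replicate 1 or 2 (0.105), and HMMR without PLK2 replicate 1 or 2 (0.115). With the preset correlation the list was called with any library left out. PLK1 was at 0.12 (SE 0.06, adjusted p = 0.305), and passed without Vector replicate 1 (adjusted p = 0.000992) and with GC content and length trends removed (0.00701). None of the 42 genes of G1/S and DNA replication passed the test (0 adjusted over the list alone, adjusted p = 0.279 for the list).

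Other lists held few or no called genes. Of 35 p53 targets, PLK2 itself and the growth arrest gene GADD45A (0.39, SE 0.07, adjusted p = 0.0117) rose, and 28 members lay above 0. Adjusted over the list alone 9 were higher and 1 lower, and the list's adjusted p was 8.13e-06, or adjusted p = 0.0360 with an estimated correlation. Without PLK2 in the list, adjusted p = 0.0860 with an estimated correlation. The immediate-early gene EGR1 rose by 1.05 (SE 0.14, adjusted p = 0.00237), alone among 35 members, with 3 higher when adjusted over the list alone and adjusted p = 0.299 for the list, or 0.0420 without Vector replicate 1. ANKRD1, a target of the Hippo effector YAP, rose by 1.06 (SE 0.07, adjusted p = 1.40e-06), alone among 28 TGF-beta and Hippo targets (adjusted p = 0.273 for the list). PPP1R15A, which directs dephosphorylation of eIF2α, rose by 0.52 (SE 0.08, adjusted p = 0.00762), alone among 39 genes of the unfolded protein and ATF4 response (adjusted p = 0.818 for the list), and POC5 rose by 0.45 (SE 0.08), alone among 27 centriole genes. H3C6 and H2BC5 rose among 13 histone genes, which all lay above 0 (adjusted p = 6.88e-05 for the list, adjusted p = 0.376 with an estimated correlation), though histone genes have near-identical copies and largely lack poly(A) tails. The lists of centriole genes (higher, 21 of 27 above 0, adjusted p = 0.0119) and of glycolysis and hypoxia genes (lower, 8 of 33 above 0, no gene called, adjusted p = 0.00303) both had adjusted p = 0.673 with an estimated correlation. With the preset correlation the centriole list had adjusted p = 0.161 without Vector replicate 1 and the glycolysis list 0.0931 without PLK2 replicate 2. Without PLK2 replicate 2, GADD45A (0.101), PPP1R15A (0.0943), POC5 (0.104), H3C6 (0.0660) and H2BC5 (0.0859) did not pass. GADD45A also did not pass without Vector replicate 3 or PLK2 replicate 1 or 3, nor POC5 without PLK2 replicate 3.

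The genes of the chaperone named in the series title did not pass the test with all libraries. RNA levels in HEK293T cells do not show the level, phosphorylation or binding of the HSP90α and IKKβ proteins. Nor do they bear on microglia. HSP90AA1, which encodes HSP90α, was at 3626 ± 358 CPM in Vector and 3956 ± 134 CPM in PLK2 libraries (SD, n = 3 each), a log2 fold change of 0.13 (SE 0.06, adjusted p = 0.330). It passed in 1 of 17 alternatives, without Vector replicate 2 (adjusted p = 0.0494). HSP90AB1 was at -0.05 (SE 0.05, adjusted p = 0.602). None of the 21 tested HSP90 chaperones and co-chaperones passed in PLK2 vs Vector, over all genes or adjusted over the list alone, and the list had adjusted p = 0.293. Among 31 heat shock genes, the inducible chaperone HSPA6 rose by 2.38 (SE 0.40, adjusted p = 0.0105), from 0.352 ± 0.14 to 1.90 ± 0.51 CPM, but not without PLK2 replicate 2 or 3 (highest adjusted p = 0.101). The list had adjusted p = 0.489.

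**Figure D2:**
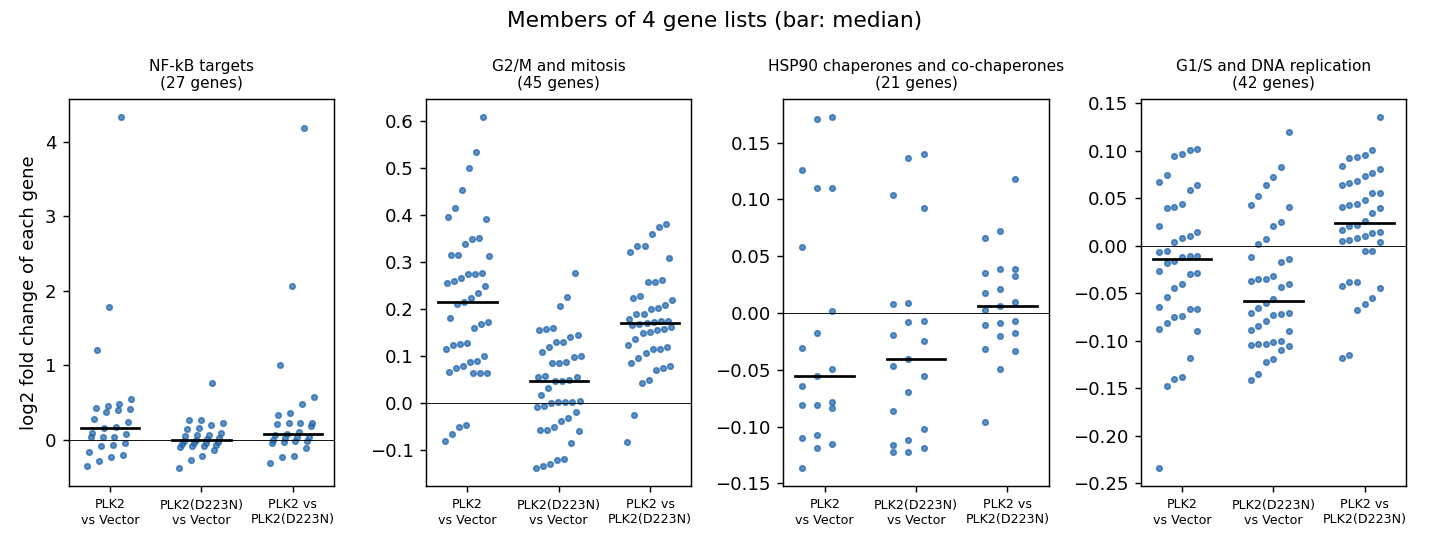
Log2 fold change (vertical axes, ranges differ between panels) of each tested member of 4 gene lists in the 3 comparisons, with a bar at the median. For the G2/M genes the medians are 0.21 in PLK2 vs Vector, 0.05 in PLK2(D223N) vs Vector and 0.17 in PLK2 vs PLK2(D223N), and for the HSP90 list they lie between -0.06 and 0.01.

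The number of genes called in PLK2 vs Vector depended on the Vector libraries. It was 363 (310 higher, 53 lower) without Vector replicate 1 and 1656 (1205 higher, 451 lower) without Vector replicate 2, and it was 22, 13 and 20 without PLK2 replicates 1, 2 and 3. With trends in GC content and length removed it was 295, of which 245 were higher and 50 lower, against 62 and 4. Of 28 named genes that passed besides PLK2, 9 passed under each alternative run for them, namely TNFRSF9, DNAH17, PLA2G4C, RELB, TNFAIP3, DHRS2, CYLD, EGR1 and ANKRD1. Fitted to the 6 Vector and PLK2 libraries alone, the 4 lower genes, TP63, FILIP1L, GADD45A, HJURP, AURKA, HMMR, KIF18A and POC5 did not pass, with adjusted p between 0.0538 and 0.121.

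With PLK2(D223N), few genes changed against Vector. PLK2 aside, EGR1, a transcription factor induced early by growth signals, rose from 2.69 ± 0.018 to 6.09 ± 0.70 CPM (SD, n = 3 each), a log2 fold change of 1.18 (SE 0.14, adjusted p = 0.00228). ATF3, a stress-induced transcription factor, rose by 0.48 (SE 0.07, adjusted p = 0.0261), but with a library left out it passed only without Vector replicate 1 or 2, and adjusted p reached 0.270 without PLK2(D223N) replicate 1. In a fit to the 6 Vector and PLK2(D223N) libraries alone it was 0.439. With all libraries and the settings given above, edgeR called no gene lower, while 427 genes were lower at an unadjusted p below 0.05 and DESeq2 called 1 lower and 8 higher. A share of 0.05 of unchanged genes would also pass the unadjusted threshold, so the 427 are not a count of changed genes. Lower genes numbered 1 with a replicate block, 1 without a filter, 2 without Vector replicate 1 and 24 without Vector replicate 2. Genes that led with PLK2 did not behave alike here, and EGR1 and PLK2 aside none of those named passed. The log2 fold change was -0.27 (SE 0.20) for RELB, -0.03 (SE 0.38) for DNAH17, 0.11 (SE 0.28) for PLA2G4C and 0.20 (SE 0.10) for TNFAIP3. TNFRSF9 had 8 counts with PLK2(D223N) and 7 in Vector libraries, a ratio of 1.12 with an exact 95% counting interval of 0.354 to 3.62. Others lay further from 0, with ANKRD1 at 0.30 (SE 0.08), NPR3 at 0.45 (SE 0.28), TP63 at 0.48 (SE 0.31), FILIP1L at 0.77 (SE 0.27) and RGPD2 at 1.32 (SE 0.42), with adjusted p between 0.509 and 0.607. Of the 65 genes other than PLK2 called in PLK2 vs Vector, 57 had the same direction here, with a median of 0.17 in that direction against 0.52. Both comparisons share their Vector libraries, so this agreement is no test of a common effect.

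None of the 27 NF-kB targets passed in PLK2(D223N) vs Vector (0 adjusted over the list alone, adjusted p = 0.957 for the list by camera), and none of the 45 G2/M genes did (0 adjusted over the list alone, adjusted p = 0.346, or adjusted p = 0.0243 without Vector replicate 2). HSP90AA1 was at 0.01 (SE 0.06) and IKBKB at 0.06 (SE 0.07). The 21 HSP90 genes had a median of -0.04 with no gene called and adjusted p = 0.0473 as a list, or adjusted p = 0.443 with an estimated correlation. That list was not called without Vector replicate 1, 2 or 3, PLK2(D223N) replicate 1 or 2 or PLK2 replicate 1, with adjusted p between 0.0525 and 0.117. By camera with the preset correlation 11 lists were called, 3 higher and 8 lower. The 56 cytosolic ribosomal protein genes had a median of -0.08 and adjusted p = 3.01e-08. With an estimated correlation no list was called, and adjusted p = 0.443 for the ribosomal list, which had 0.127 with the preset correlation without Vector replicate 1. The count of 3 genes became 21 (19 higher, 2 lower) without Vector replicate 1 and 347 (323 higher, 24 lower) without Vector replicate 2. EGR1 passed under each alternative run, and ATF3 lost its call in 8 of 17.

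PLK2 vs Vector and PLK2(D223N) vs Vector had 2 genes in common, PLK2 and EGR1, both higher. Independent lists of these lengths would share 0.0144 higher genes. PLK2 is the transgene, and without it the overlap is 1 gene, where independent lists would share 0.00944. Both comparisons use the same Vector libraries, and simulated unchanged groups shared between 0 and 1 genes, with a mean of 0.1 over 60 simulations, so an overlap of 1 lies in the simulated range. Across genes, with PLK2 left out, the fold changes of both comparisons correlated at 0.67, where simulated unchanged groups gave 0.61 (0.59 to 0.64), and genes are not independent replicates. The covariance was 0.0278 against a simulated 0.0130, while 76.7% of genes had the same sign against a simulated 78.1% (76.9 to 78.8). The Vector libraries are too few to be split. The simulation already shared them between both comparisons, but it drew genes independently. It thus left out trends common to many genes, such as those with GC content. The simulated ranges may be too narrow, so the excess in correlation decides nothing. The overlap was 12 genes without Vector replicate 1 and 320 without Vector replicate 2.

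**Figure D3:**
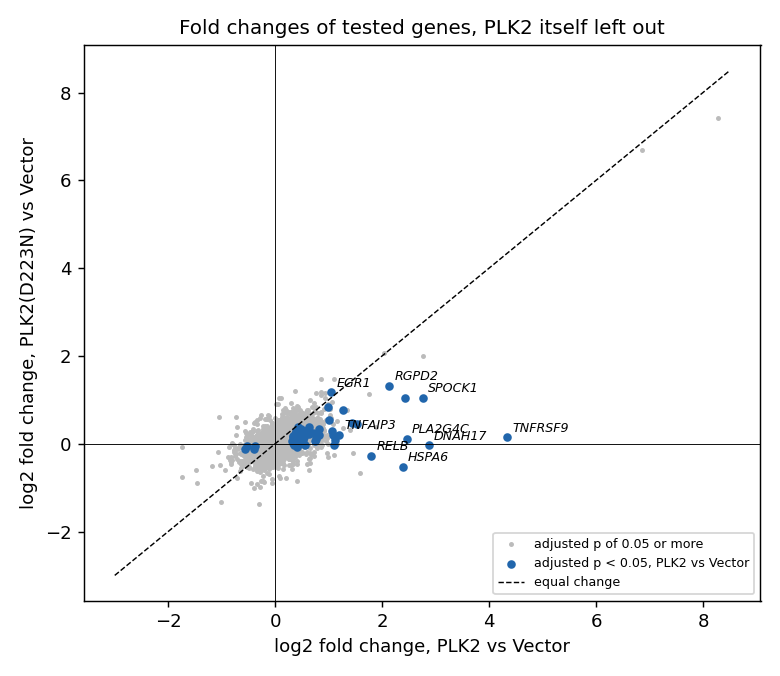
Log2 fold change in PLK2(D223N) vs Vector (vertical) against that in PLK2 vs Vector (horizontal) for each tested gene but PLK2, with genes called in PLK2 vs Vector in blue and a dashed line of equal change. TNFRSF9, DNAH17, PLA2G4C and RELB lie far right and near 0 on the vertical axis, while EGR1 lies near the line. The grey points at the upper right, SULT1A4 and STIMATE-MUSTN1, share sequence with other genes and did not pass the test.

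The direct comparison of PLK2 with PLK2(D223N) tests which changes differed between the intact and the substituted kinase. Of 12924 genes, 20 were higher and 1 lower with PLK2. At an unadjusted p below 0.05 by the same test, 385 were higher and 396 lower. A share of 0.05 of unchanged genes would also pass there, so these are not counts of changed genes. TNFRSF9 had the largest rise, with 148 against 8 counts, a ratio of 19.0 with an exact 95% counting interval of 9.39 to 44.8. RELB rose from 1.38 ± 0.14 to 5.77 ± 0.38 CPM (SD, n = 3 each), a log2 fold change of 2.06 (SE 0.16, adjusted p = 1.14e-05). DNAH17 (2.90, SE 0.26), PLA2G4C (2.35, SE 0.20), DHRS2 (1.04, SE 0.11) and TNFAIP3 (1.00, SE 0.09) rose with adjusted p between 2.37e-05 and 0.000269. The only gene called lower was the homeobox gene HOXB6 (-0.36, SE 0.07, adjusted p = 0.0382), which did not pass without Vector replicate 3 or any 1 PLK2 or PLK2(D223N) library (highest adjusted p = 0.309), nor with a replicate block (0.0854). EGR1 did not pass, at -0.13 (SE 0.12, adjusted p = 0.943), nor did NPR3 (1.08, SE 0.22, adjusted p = 0.0891), TP63 (0.318), RGPD2 (0.715) or FILIP1L (0.820).

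Of the 27 NF-kB targets, 6 rose in PLK2 vs PLK2(D223N), none fell and 21 did not pass, and adjusted over the list alone 7 were higher and none lower. NFKB2 rose by 0.57 (SE 0.09, adjusted p = 0.00840), NFKBIA by 0.47 (SE 0.09, adjusted p = 0.0388) and CYLD by 0.33 (SE 0.06, adjusted p = 0.0382). These were the weaker members. NFKBIA and CYLD did not pass without Vector replicate 3 or any 1 PLK2 or PLK2(D223N) library (highest adjusted p = 0.343 and 0.339), nor CYLD with a replicate block (0.0624), nor NFKB2 without PLK2(D223N) replicate 2 or 3 or any 1 PLK2 library (0.107). The list had a mean of 0.35 but a median of 0.08, since few members carry it, and adjusted p = 4.56e-10, or adjusted p = 0.00656 with an estimated correlation. The signalling components had adjusted p = 0.0107 and a mean of 0.11 but a median of -0.01, and adjusted p = 0.102 with an estimated correlation. Of the 45 G2/M genes, HJURP (0.38, SE 0.05, adjusted p = 0.00490) and AURKA (0.33, SE 0.05, adjusted p = 0.0158) rose and 43 did not pass. HJURP did not pass without PLK2(D223N) replicate 1 or 2 or PLK2 replicate 2 (highest adjusted p = 0.0640), nor AURKA without any 1 PLK2(D223N) library or PLK2 replicate 1 or 2 (0.201). Adjusted over the list alone 26 were higher and none lower, and the list had adjusted p = 1.11e-29, or adjusted p = 0.00656 with an estimated correlation. PLK1 was at 0.26 (SE 0.06, adjusted p = 0.137), and passed in 6 of 17 alternatives, among them those without Vector replicate 1 (adjusted p = 5.00e-07) and 2 (0.0307) and the fit to the 6 libraries compared (4.31e-09).

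ANKRD1 (0.76, SE 0.07, adjusted p = 3.51e-05), H3C6 (0.89, SE 0.16), GAS2L3, a cytoskeletal linker (0.68, SE 0.11), and CREBRF, a regulator of CREB3 (0.62, SE 0.08), were also higher with PLK2 than with PLK2(D223N). HSPA6 rose by 2.90 (SE 0.43, adjusted p = 0.00700) and PPP1R15A by 0.44 (SE 0.08, adjusted p = 0.0382). H3C6 did not pass without PLK2(D223N) replicate 2 or 3 or any 1 PLK2 library (highest adjusted p = 0.250), GAS2L3 without PLK2(D223N) replicate 2 or 3 or PLK2 replicate 2 or 3 (0.169), HSPA6 without PLK2(D223N) replicate 1 or 2 or PLK2 replicate 2 or 3 (0.0740), and PPP1R15A without Vector replicate 3 or any 1 PLK2 or PLK2(D223N) library (0.3198). None of the 21 HSP90 genes passed in this comparison (0 adjusted over the list alone), with adjusted p = 0.482 for the list. HSP90AA1 was at 0.12 (SE 0.06, adjusted p = 0.866), and passed in 2 of 17 alternatives, the fit to the 6 libraries compared (adjusted p = 0.0109) and without Vector replicate 1 (0.0264). IKBKB was at -0.05 (SE 0.07) and passed in none of 17. The Notch target HES1 was at -0.49 (SE 0.09, adjusted p = 0.0568) and passed in 7 of 17 alternatives, among them those without Vector replicate 1 (adjusted p = 0.000500) and 2 (0.0122). The list of 21 Notch and Wnt targets was lower with adjusted p = 0.00115, or adjusted p = 0.162 with an estimated correlation. In all 12 lists were called with the preset correlation, and the NF-kB targets and G2/M genes alone held with an estimated correlation. With GC content and length trends also removed, the NF-kB signalling components were called too (adjusted p = 0.0409 by camera with an estimated correlation). Before that removal, 15 of the 32 signalling components lay above 0 and 4 were called. These were RELB, NFKB2, CYLD and NFKBIA, which the list of targets also holds, so this list is no separate evidence.

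The spread of the Vector libraries entered this comparison through the shared model. Fitted to the 6 PLK2 and PLK2(D223N) libraries alone, 502 genes were called, 374 higher and 128 lower, among them all 21 genes above. Leaving out Vector replicate 1 gave 317 genes and Vector replicate 2 gave 54, while leaving out PLK2(D223N) replicates 2 and 3 gave 9 and 12, and PLK2 replicates 1, 2 and 3 gave 13, 10 and 12.

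No marker of other cell types passed the gene test over all genes. Without TMM scaling, the macrophage and microglia markers summed to 4.18 ± 0.45 CPM in Vector, 2.86 ± 0.49 in PLK2(D223N) and 4.10 ± 0.17 in PLK2 libraries. Adjusted over that list alone, 1 of its 2 tested genes was lower in PLK2(D223N) vs Vector and 1 was higher in PLK2 vs PLK2(D223N). Of the 2 tested macrophage and microglia genes, ITGAM was at 1.95 ± 0.18 CPM in Vector, 1.05 ± 0.51 in PLK2(D223N) and 1.88 ± 0.055 in PLK2 libraries (SD, n = 3 each), with adjusted p = 0.611 between the constructs. The lymphocyte markers, also without TMM scaling, summed to 2.98 ± 0.097 CPM in Vector, 2.76 ± 0.11 in PLK2(D223N) and 2.48 ± 0.22 in PLK2 libraries. None of the 6 fibroblast genes or of the 4 keratin and cadherin genes passed in any comparison.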

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

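Alternatives with GC content and length trends removed, with limma on TPM, with PLK2 out of the lists, and with an estimated correlation without Vector replicate 1 were chosen after seeing the data. The fold changes of PLK2 kept their direction and call throughout. The counts depended on which libraries were included, most of all on the Vector libraries, and the cause of these differences was not tested. Genes changed in PLK2 vs Vector, PLK2(D223N) vs Vector and PLK2 vs PLK2(D223N), in this order, numbered 143, 9 and 37 by the DESeq2 Wald test, 136, 5 and 35 without a filter, 274, 6 and 64 with the GC trend removed, and 295, 6 and 80 with GC and length trends removed. With the 6 libraries compared alone the first and last were 23 and 502, and with limma on log2(TPM + 1) they were 19 and 11. Leaving out each library in turn gave between 13 (without PLK2 replicate 2) and 1656 (without Vector replicate 2), between 2 and 347 (without Vector replicate 2), and between 9 (without PLK2(D223N) replicate 2) and 317 genes (without Vector replicate 1). The overlap was 4 genes by DESeq2 and between 2 and 320 with a library left out.

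Whether samples that share a replicate number also share a batch is not known here. Their deviations from the group means correlated between -0.11 and 0.13, against -0.21 to 0.11 for samples with other numbers. These few pairs cannot exclude a pairing. A replicate block gave 76, 4 and 20 genes, an overlap of 2 genes, and the same calls for the lists of NF-kB targets and G2/M genes. Lists called, in the same order, numbered 6, 11 and 12 with the preset correlation, and 3, 0 and 2 with an estimated one. They were 2, 0 and 2 with an estimated correlation without Vector replicate 1 or with PLK2 out of the lists, and 3, 0 and 3 with trends removed. With a library left out the D223N count was between 4 (without Vector replicate 1) and 11. The lists of NF-kB targets and G2/M genes stayed called in PLK2 vs Vector and PLK2 vs PLK2(D223N) in each of the 17 alternatives run for lists, and the HSP90 list stayed uncalled in both. List tests with a library left out used the preset correlation, and only that without Vector replicate 1 was repeated with an estimated one. Lists were not run with the DESeq2 Wald test, no filter, the 6 libraries alone, PLK2 removed before scaling, the GC trend alone or TPM. In PLK2(D223N) vs Vector the HSP90 list was called in the first fit and in 5 of 17 alternatives. Without Vector replicate 1, the ribosomal protein list turned from lower to higher in PLK2 vs Vector (adjusted p = 2.25e-06), while it was called lower without Vector replicate 2 (0.000621) and without PLK2 replicate 2 (0.0387). The autophagy and lysosome list also turned without Vector replicate 1 (adjusted p = 0.0488), and neither was called there with an estimated correlation (adjusted p = 0.620 and 0.386). With a library left out, the adjusted p of these lists lay between 2.25e-06 and 0.557 and between 0.0488 and 0.992.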

Other observations

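The tests of the transgene level, of the share of cells in mitosis, of Vector replicate 1 and of GC content and length were chosen only after seeing the data, and for GC content and length the bounds were set before that test was run. Among genes too low to test, IL32, singled out after its values were seen, had 24 counts over the PLK2 libraries against 2 in Vector and 2 in PLK2(D223N) libraries, a ratio to Vector of 12.04 with an exact 95% counting interval of 2.99 to 105.1, and BCL2A1 had 4 against 0 and 0. Both are on the list of NF-kB targets, whose other untested members did not all rise. In Vector, PLK2(D223N) and PLK2 libraries TNFAIP2 had 21, 17 and 13 counts, IL23A 22, 28 and 20, and CXCL3 9, 13 and 8. An interval for a gene picked by its values does not keep its 95% coverage, so these counts say nothing about the list as a whole. Of the 65 genes other than PLK2 called in PLK2 vs Vector, 18 were also called between PLK2 and PLK2(D223N).

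Genes of the NF-kB list were higher with PLK2 than with PLK2(D223N). PLK2 RNA was also 1.92-fold higher there. A rise in proportion to that RNA would put the 27 tested members at a mean log2 fold change of 0.26 in PLK2(D223N) vs Vector. The measured mean was 0.03, a shortfall of 0.23 (SE 0.13 over members and 0.04 over libraries, median 0.04). With trends in GC content and length removed it was 0.24 (SE 0.13 and 0.03). The shortfall exceeded 2 SE over libraries but not over members, which are genes of 1 list and not replicates. The shortfall was 1.01 (SE 0.50) over the 6 members called between the constructs, which were selected by that difference and so decide nothing, and 0.01 (SE 0.03) over the other 21. Removing trends with GC content and length left the list called (adjusted p = 0.00561 with an estimated correlation, mean 0.35 before and 0.37 after, both with SD 0.89 and median 0.08), which argues against those trends as the whole cause. The other 21 had a mean predicted value of 0.04, so they could hardly show a shortfall. The mean shortfall of the list thus rests on few members, and a proportional response stays open for the list as a whole. A response that starts only above some level of PLK2 RNA cannot be told apart from a need for the intact kinase domain. Each construct was present at a single level. A role of kinase activity may thus be put forward as a hypothesis only.

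The list of G2/M genes was higher with PLK2 than with PLK2(D223N), with a log2 fold change above 0 in 43 of 45 members, of which 2 passed the gene test. With GC content and length trends removed the list stayed called (adjusted p = 0.00300 with an estimated correlation), and its mean went from 0.18 (SD 0.10) to 0.16 (SD 0.099), which argues against these trends as the whole cause. A rise in proportion to PLK2 RNA would put the members at a mean of 0.12 in PLK2(D223N) vs Vector, where 0.04 was measured, a shortfall of 0.0793 (SE 0.00917 over members and 0.0192 over libraries, or 0.0854 with SE 0.00880 and 0.00797 with trends removed), which argues against a proportional response as the whole cause. A larger share of cells in G2 or M phase and higher RNA per cell cannot be told apart in RNA of whole cultures. A response that starts only above some level of PLK2 RNA also stays open, since each construct was present at one level.

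In PLK2 vs Vector there were 15.5 higher calls for each lower call. Without Vector replicate 1 there were 5.85, and between 5.79 and 11.2 with any further library also left out. This argues against Vector replicate 1 as the whole cause. Without Vector replicate 2 there were 2.67. At an unadjusted p below 0.05 there were 1235 higher and 880 lower of 12924 genes. A share of 0.05 of unchanged genes would also pass there, on either side alike, which draws the ratio towards balance. The size of the imbalance thus depends on the Vector libraries and the threshold. With GC content and length trends removed there were 4.90 higher calls for each lower call, between the bounds set beforehand. It thus stays open how far those trends cause the imbalance. Fold changes in that comparison correlated with GC content at -0.46 across genes, which are not independent replicates, and libraries ran from 0.62 in Vector replicate 1 to -0.39 in PLK2 replicate 2. Removing the trends took out 53.4% of the variance between Vector replicates 1 and 2 and 0.897% of that between PLK2(D223N) replicates 1 and 2. Part of the spread between the Vector libraries may thus be a technical trend, among other candidates.

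Of the 10 splits of 6 libraries into 3 and 3, which are too few for a share under 0.05, only 1, the real one, gave as many genes in each comparison. The real split gave 66 genes in PLK2 vs Vector and the highest other split 0. The values were 3 and 0 in PLK2(D223N) vs Vector, and 21 and 1 in PLK2 vs PLK2(D223N).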
